A study of Mus musculus with 30 samples.

How the data were processed

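Bulk RNA sequencing of polyA-selected RNA was available for 30 libraries of mouse bone marrow-derived macrophages of 2 genotypes (WT and TRα1PV) in 3 states (M0, M1 and M2), with 5 biological replicates per group. Per the labels, cells were cultured for 7 days with L929-conditioned medium at 15 or 20%. The deposited values are raw read counts per Ensembl gene, made by the authors with HTSeq 1.99.2 from 1 library each and not normalized. Their processing notes also name the mouse genome GRCm39, Trimmomatic 0.39, HISAT2 2.2.1, FastQC 0.11.9, Cufflinks, edgeR, limma and R 4.3.2, without a role or order for each. The annotation release and the strand setting of the counting are not given in the sources used here. Each file held 55414 genes and 5 totals of reads given to no gene. The reference at hand was a different genome build and served for gene symbols and gene neighbours only, so no coordinates are given, and 52081 of the 55414 genes received a symbol.

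Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 15686. Libraries were scaled with TMM factors, and all 30 entered 1 quasi-likelihood fit with a mean per group and 24 residual degrees of freedom. The comparisons were TRα1PV against WT in each state, M1 and M2 against M0 in each genotype, and the difference of the genotype effect in M1 or M2 from that in M0. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, with no minimum fold. Standard errors were derived from this fit, as the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. They are approximate, above all for genes with few reads in a group. A fold against a group with no read used a floor of 3 counts over the group, and 1 to 3 reads were given as a ratio with a 95% exact interval. Measures per library were compared between genotypes with exact permutation tests over 252 arrangements, where 0.00794 is the smallest p that 5 against 5 can give, in a family of 27 tests. None of these passed adjustment (smallest adjusted p = 0.143).

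Gene lists were written from general knowledge, 38 lists with 718 symbols, of which 31 had at least 5 tested members. Of these symbols, 15 were replaced by their current names after the data were seen. Lists were tested with limma's camera at a preset correlation of 0.01 on voom values, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether the list's genes move, on balance, one way. Markers of B cells (2 tested members), T and NK cells (1), mast cells and basophils (1), eosinophils (3), erythroid cells (1) and endothelium (4) and the sex-linked genes (1) were too few for a list test. The tests, lists, alternatives and the rule for named genes were chosen before the data were examined.

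The rule named Thra and Thrb, and in each genotype comparison the 8 called genes with the largest change at a mean log2 CPM of at least 0 and with 1 sign in all 5 same-numbered pairs. It added the 8 with the smallest p and up to 4 members of each list that passed or held a called gene. For polarization it took the 5 largest increases and decreases and up to 4 members of 3 lists, and for differences of the genotype effect the 6 genes with the smallest p. Of the list members that the rule allowed, the text names a part, picked for length after the values were seen, and some genes named by the rule are not reported here. A predicted gene model with no name was passed over for the next gene once among the decreases with M1 in WT, once among the increases and once among the decreases with M1 in TRα1PV.

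Alternatives were median-of-ratios (RLE) size factors, DESeq2, limma-voom, no filter on low counts, only the libraries of the compared groups, a replicate block, a block within genotype for the comparisons between states, and leaving out each library in turn. The share of reads outside genes as a covariate, and leaving out both M0 libraries numbered 2 or WT M0 replicate 2 from the list tests, were chosen after seeing the data. The labels number the biological replicates 1 to 5 in each group, under the tag batch, and whether a number stands for 1 animal or day is not stated. Deviations from the group means correlated between same-numbered WT and TRα1PV libraries by -0.37 to 0.26 in M0, -0.17 to 0.17 in M1 and -0.02 to 0.21 in M2. Between states of a genotype, M0 with M1 or M2, they did so by -0.24 to 0.33. The highest mean was 0.184 for TRα1PV M0 with M2 (-0.0459 for other numbers), where 4 of 5 libraries correlated best with their own number. Every pair of libraries of a group differed beyond counting noise (chi-square per degree of freedom 6.67 to 209 over 60 pairs). Xist ranged from 476 to 1498 CPM over the 30 libraries, and Y-linked genes had at most 2 reads in a library.

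The steps were tested on simulated data with the dispersion of these libraries, in which 200 of 15686 genes were changed between the M0 groups. The quasi-likelihood fit found 66% of genes changed 1.5-fold and 78% of those changed 2-fold, and 4 of 15456 unchanged genes were called, 2.61% of its calls. limma-voom found 66 and 75% with 6.92% of its calls false, and DESeq2 69 and 76% with 8.43% false. A list raised 1.3-fold was called (adjusted p = 2.35e-17, and adjusted p = 1.3e-08 with an estimated correlation), and the other 30 lists did not pass. The simulated genes were drawn independently, without correlation between genes or a quality trend between libraries. The rates found, those of the lists above all, may therefore not hold for the real libraries.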

Results

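Gene expression was measured by polyA-selected RNA sequencing in mouse bone marrow-derived macrophages, which are macrophages grown from bone marrow in medium conditioned by L929 fibroblasts. Cells came from wild-type (WT) mice and from mice carrying TRα1PV, a mutant form of thyroid hormone receptor α1 that does not bind thyroid hormone (T3) and acts in a dominant-negative manner. After 7 days of culture, cells were left unstimulated (M0), given lipopolysaccharide (LPS) together with interferon-γ, each at 20 ng/mL (M1), or given interleukin-4 at 20 ng/mL (M2). Each of the 6 groups held 5 libraries from biological replicates, 30 in all. Between 23016000 and 59086000 reads per library, rounded to 5 digits, were counted in genes, and 15686 genes were tested. Values below are log2 fold changes from edgeR ± a standard error derived from its F statistic, with 5 libraries per group. Levels are given as mean ± SD in CPM, which are read counts scaled to a common library size.

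The first principal component held 71.8% of the variance and set the M1 libraries apart from the others, and the second held 14.6% and set M0 apart from M2. Within each state the genotypes lay side by side, without overlap on the second component in M0 and on the first in M1 and in M2.

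**Figure D1:**
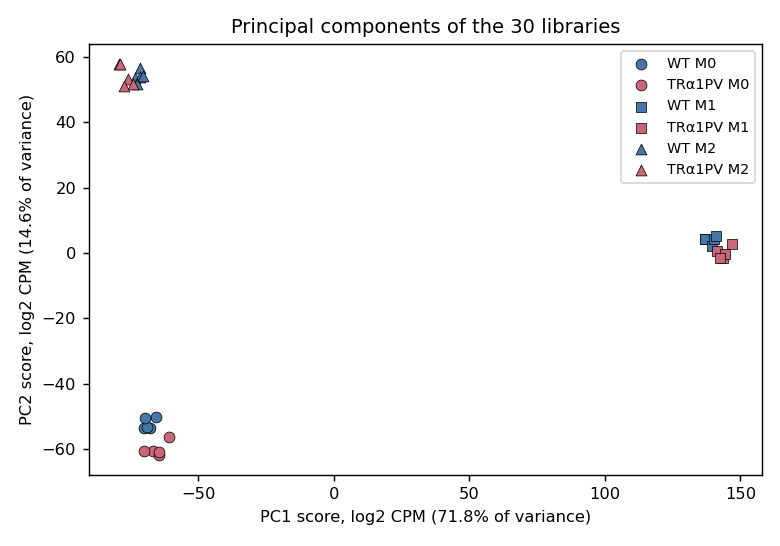
Scores of the 30 libraries on the first and second principal components of log2 CPM, with 71.8% and 14.6% of the variance on the axes. Colours stand for genotypes and symbols for states, and each point is 1 library. The libraries form a cluster per state, with the genotypes side by side in each.

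Thra, the gene that encodes thyroid hormone receptor α (ENSMUSG00000058756), had more reads in TRα1PV than in WT in every state. It stood at 56.1 ± 4.03 CPM in TRα1PV and 24.5 ± 1.91 CPM in WT in M0, at 49.2 ± 3.59 and 25.7 ± 6.06 CPM in M1, and at 43.4 ± 1.79 and 16.8 ± 0.93 CPM in M2. The log2 fold changes were 1.20 ± 0.10, 0.94 ± 0.10 and 1.37 ± 0.10 (adjusted p = 1.76e-10, 7.95e-08 and 2.24e-11), and the 5 TRα1PV libraries lay above the 5 WT libraries in each state. Counts per gene do not separate mutant from normal transcripts or the receptor isoforms, so they do not check the mutation itself. Nr1d1, whose transcript overlaps Thra on the other strand, stood at 10.8 ± 0.718 CPM in TRα1PV and 9.04 ± 1.41 CPM in WT in M0, at 6.55 ± 0.721 and 3.78 ± 1.12 CPM in M1, and at 5.55 ± 0.963 and 4.56 ± 0.786 CPM in M2. Because the strand setting of the counting is not given in the sources used here, how reads in the overlap were assigned cannot be settled from the counts. Thrb, which encodes thyroid hormone receptor β, was scarce in M0 and M1 and reached 4.86 ± 0.641 CPM in TRα1PV and 4.94 ± 1.24 CPM in WT in M2. Its log2 fold change between genotypes was -0.86 ± 0.31 in M0 (adjusted p = 0.0418) and -0.03 ± 0.19 in M2 (adjusted p = 0.944). In M1 it had 2 reads in the TRα1PV group and 1 in the WT group, too few for a fold. Leaving out WT M0 replicate 1, 2, 3 or 4 or TRα1PV M0 replicate 1, 2, 4 or 5 ended the M0 call of Thrb (adjusted p = 0.0844 without the first of these), and its adjusted p ranged from 0.00352 to 0.12 over 18 alternatives.

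**Figure D2:**
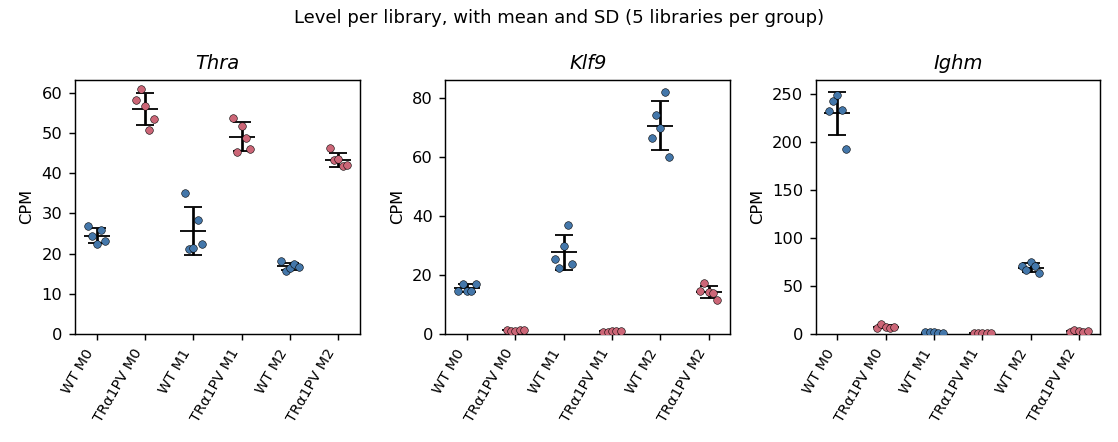
Level in CPM of Thra, Klf9 and Ighm in each of the 30 libraries (points), by genotype and state, with the mean and SD of the 5 libraries per group (black). Thra was higher in TRα1PV in each state, Klf9 was lower in each state, and Ighm was lower in M0 and M2.

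LPS with interferon-γ raised inflammatory genes in both genotypes. In WT, the chemokine gene Cxcl11 rose by 11.84 ± 0.25, Nos2, which encodes inducible nitric oxide synthase, by 11.42 ± 0.48, Il12b, a subunit of interleukin-12, by 11.29 ± 0.44 and Coch by 11.20 ± 0.36. Ptgs2os, a transcript beside Ptgs2, had no read in WT M0 and was at least 641-fold higher in M1. The organic anion transporter gene Slco2b1 changed by -9.52 ± 0.26, Angptl4 by -9.12 ± 0.38 and the adhesion receptor gene Adgre4 by -9.04 ± 0.21. Nwd1 had no read in WT M1 and was at least 99.3-fold lower, and Agmo had 1 read there, a ratio of 664 (95% exact interval 119 to 26267). In TRα1PV, the increases included Nos2 (11.70 ± 0.49), Cxcl9 (11.15 ± 0.38), Il12b (11.02 ± 0.44), Upp1 (10.90 ± 0.26) and Ptgs2os, at least 541-fold. The decreases there included Slco2b1 (-10.33 ± 0.25), Adgre4 (-9.91 ± 0.22) and Hpgd (-9.41 ± 0.32), with Elane at least 134-fold lower and Abca6 at 1 read in M1, a ratio of 1483 (266 to 58597). These bounds and intervals cover counting error only and use a floor of 3 reads per group. Elane is a granulocyte-precursor marker, and other markers of such cells moved with it. With a replicate block, 10 markers of that list were lower and 2 higher in TRα1PV (camera adjusted p = 0.0123), although the list did not pass without the block.

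Among the gene lists, 24 of 25 classical activation genes rose in WT and 1 fell (24 and 1 adjusted over the list alone). Those that rose included Il15ra (4.99), Cd40 (6.93), Ptgs2 (10.73) and Slamf7 (3.92). The same numbers rose and fell in TRα1PV, with Il15ra at 4.80, Cd40 at 6.43, Ptgs2 at 10.44 and Slamf7 at 4.22. The camera adjusted p was 1.24e-10 in WT and 1.61e-09 in TRα1PV, and 0.0732 and 0.124 were the adjusted p with an estimated correlation. Of the cytokine and chemokine genes, 17 of 23 rose in WT and 17 in TRα1PV (17 and 17 adjusted over the list alone), while 5 and 4 fell (5 and 4 over the list alone). The genes that rose included Cxcl16 (2.52 in WT and 2.67 in TRα1PV), Ccl5 (9.79 and 9.12) and Il27 (6.23 and 6.24), and Cxcl11 was at 10.49 in TRα1PV. The list had an adjusted p of 5.34e-04 and 5.33e-04, and of 0.278 and 0.365 with an estimated correlation. The alternative activation list did not move as a whole (adjusted p = 0.876 and 0.905), and its members went both ways: Klf4 rose by 5.75 in WT and 5.34 in TRα1PV and Slc7a2 by 6.13 and 5.61, while Clec10a changed by -6.06 and -5.94 and Mrc1, the mannose receptor gene, by -5.72 and -5.78. Thrb fell to 1 read in WT M1 and 2 in TRα1PV M1, while Thra changed by 0.07 ± 0.10 in WT (adjusted p = 0.511) and -0.19 ± 0.09 in TRα1PV (adjusted p = 0.0653). The Thra change in TRα1PV passed in 6 of 19 alternatives, among them the fit with a replicate block (adjusted p = 0.0295, range 0.0062 to 0.175). In all, 6184 genes were higher and 6303 lower in WT M1 than in M0, and 6275 were higher and 6383 lower in TRα1PV.

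Interleukin-4 raised the genes of alternative activation in both genotypes. In WT, Rnase2a rose by 10.63 ± 0.22, the potassium channel gene Kcnd3 by 10.07 ± 0.26, Retnla, a secreted marker of alternatively activated macrophages, by 10.04 ± 0.38 and Arg1, which encodes arginase, by 9.69 ± 0.31. Chil4 had no read in WT M0 and was at least 270-fold higher in M2. In TRα1PV, Arg1 rose by 11.11 ± 0.34, the sodium channel gene Scn3a by 11.10 ± 0.25, Retnla by 11.10 ± 0.39 and Rnase2a by 10.86 ± 0.22, and Kcnd3, with 3 reads in M0, had a ratio of 2530 (95% exact interval 865 to 12270). Among genes with a mean log2 CPM of at least 0, the largest decreases in WT were in Cx3cr1, the fractalkine receptor gene (-5.20 ± 0.38), the paired receptors Pilrb1 (-4.83 ± 0.28) and Pilrb2 (-4.42 ± 0.23), Fcrl1 (-4.05 ± 0.23) and Siglece (-3.82 ± 0.30). In TRα1PV they were in Cx3cr1 (-5.69 ± 0.32), Ifit3b (-5.56 ± 0.35), Pilrb1 (-5.07 ± 0.32), Ifit1bl1 (-5.0 ± 0.33) and Pilrb2 (-4.61 ± 0.25). Members of these receptor and interferon families resemble each other, and the counts do not resolve reads shared between them.

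Of the alternative activation list, 26 of 28 genes rose and 1 fell in each genotype (26 and 1 adjusted over the list alone). Those that rose included Pdcd1lg2 (8.82 in WT and 8.56 in TRα1PV), Slc7a2 (6.14 and 6.50), Mgl2 in WT (6.97) and Egr2 in TRα1PV (4.16). This list passed in WT (camera adjusted p = 1.43e-25, and adjusted p = 1.85e-04 with an estimated correlation) and in TRα1PV (adjusted p = 4.95e-21 and 5.71e-04). Cytokine and chemokine genes went both ways: Ccl9 rose by 1.80 in WT and 1.79 in TRα1PV and Ccl7 by 3.74 and 3.47, while Cxcl16 changed by -1.32 and -1.76, Ccl3 by -2.09 in WT and Cxcl10 by -4.53 in TRα1PV. Classical activation genes likewise moved in both directions, with Slamf1 at 3.67 and 3.76, Cd40 at 1.79, Ass1 at 2.03 and Ncf1 at -0.58 in WT, and Cd69 at -3.71, Tnfsf10 at -2.56 and Slamf7 at 1.10 in TRα1PV. Thrb rose by 3.76 ± 0.24 in WT and 4.59 ± 0.25 in TRα1PV, and Thra changed by -0.54 ± 0.10 and -0.37 ± 0.09. In all, 3949 genes were higher and 4264 lower in WT M2 than in M0, and 4442 were higher and 4604 lower in TRα1PV.

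The genotypes were compared first in unstimulated macrophages. Genes induced by interferons were higher in TRα1PV M0 cells: 35 of 36 tested type I interferon-stimulated genes were higher (35 adjusted over the list alone), and the remaining gene did not pass. With an estimated correlation the list did not pass (adjusted p = 0.0949). The higher genes included the antiviral factors Xaf1 (1.43 ± 0.12) and Mx1 (2.00 ± 0.18), and Parp9 (0.82 ± 0.08). Of the interferon-γ-induced GTPases and regulators, 17 of 22 tested members were higher (18 adjusted over the list alone), among them Ifi47 (1.49 ± 0.12), Gbp9 (1.43 ± 0.15) and Igtp (1.17 ± 0.12). The camera adjusted p was 2.07e-33 for the first list and 1.28e-12 for the second. The second list did not pass with an estimated correlation either (adjusted p = 0.0949). Genes of these families resemble each other as well.

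The genes with the smallest p in M0 were lower in TRα1PV. Klf9, a transcription factor gene that T3 induces, fell to 1.09 ± 0.213 CPM from 15.4 ± 1.35 (-3.81 ± 0.15, 14.1-fold lower, adjusted p = 1.09e-17). Ighm, the immunoglobulin μ heavy chain gene, fell to 7.28 ± 1.48 CPM from 230 ± 22.3 (-4.99 ± 0.16, adjusted p = 1.41e-19). The collagenase gene Mmp8 (-4.48 ± 0.23), Mmp27 (-3.38 ± 0.17), Asb4 (-5.70 ± 0.31), Rin2 (-1.59 ± 0.09), Gnptab (-1.34 ± 0.08) and Trp53inp2 (-1.02 ± 0.06) followed. For T3-responsive genes as a list, 3 members were higher and 5 lower of 15 tested (3 and 7 adjusted over the list alone), and for thyroid hormone receptors, transporters and cofactors, 7 members were higher and 4 lower of 23 tested (7 and 4 adjusted over the list alone). Neither list passed in M0 with camera (adjusted p = 0.0703 and 0.0625). With fry, which does not compare a list with the other genes, the first passed as lower (adjusted p = 2.36e-09). The second passed as higher with fry (adjusted p = 2.05e-06). Klf9 belongs to the first list and Thra to the second, and neither list was tested without them. The matrix genes Col1a2 (-5.91 ± 0.70), Bgn (-4.33 ± 0.53) and Col6a3 (-4.14 ± 0.44) and the desaturase gene Scd1 (-3.61 ± 1.08) were also among the largest decreases. Scd1 lost its call with limma-voom (adjusted p = 0.138) and with the share of reads outside genes as a covariate (adjusted p = 0.0732), and its adjusted p ranged from 1.21e-04 to 0.138.

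Marker lists of other cells passed between genotypes in M0, although none of them with an estimated correlation (smallest adjusted p = 0.204). Of the neutrophil and granulocyte-precursor markers, 10 members were higher and 2 lower of 12 tested (10 and 2 adjusted over the list alone), with S100a8 at 1.53 ± 0.30 and Mpo, myeloperoxidase, at 1.3 ± 0.30, while Mmp8 and Csf3r (-1.04 ± 0.09) were lower. Of the inflammatory monocyte markers, 5 of 10 tested members were higher (6 adjusted over the list alone), among them F13a1 (1.17 ± 0.11). Of the fibroblast and stromal markers, 7 of 8 tested members were lower (7 adjusted over the list alone), among them Sparc (-4.20 ± 0.42) and Acta2 (-1.85 ± 0.21). The adjusted p was 0.0104, 0.00211 and 8.00e-06 in this order, and 0.49, 0.251 and 0.204 with an estimated correlation.

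Metabolic lists passed as lower in TRα1PV M0 cells, although none of them with an estimated correlation (smallest adjusted p = 0.221). Of the glycolysis genes and targets of the hypoxia factor HIF-1, 16 of 28 tested members were lower (16 beside 1 higher adjusted over the list alone), among them Vegfa (-1.99 ± 0.13), Pfkfb3 (-0.86 ± 0.09), Hk3 (-0.94 ± 0.10) and the glucose transporter gene Slc2a1 (-0.88 ± 0.10). Of the nuclear genes for oxidative phosphorylation, 17 of 55 tested members were lower (19 adjusted over the list alone), with Ndufa1 at -0.54 ± 0.07. Of the tricarboxylic acid cycle genes, 9 of 20 tested members were lower (9 adjusted over the list alone), with Idh1 at -0.56 ± 0.06, and of the fatty acid oxidation genes, 5 of 21 tested members were lower (8 adjusted over the list alone). For LXR targets, 2 members were higher and 7 lower of 13 tested (2 and 8 adjusted over the list alone), with the receptor gene Nr1h3 at -1.29 ± 0.19 and Abcg1 at -0.59 ± 0.09, and for lysosomal genes, 3 members were higher and 12 lower of 30 tested (3 and 13 adjusted over the list alone), with Ctsc at 0.85 ± 0.10. The adjusted p was 1.86e-06, 6.49e-05, 0.00837, 0.00932, 0.0142 and 0.00837 in this order. With an estimated correlation, the adjusted p was 0.221, 0.561, 0.31, 0.389, 0.389 and 0.389. Beside these groups, signs of library quality differed between M0 libraries. Reads outside genes made up 13 ± 1.04% in TRα1PV and 11.4 ± 1.65% in WT (exact permutation p = 0.0952, n = 5 per group), and WT M0 replicate 2 had 13.9% and 4.56% mitochondrial reads, against 0.921% to 2.07% in the other WT M0 libraries. With the share of reads outside genes as a covariate, 11 glycolysis genes were still lower (adjusted p = 2.22e-05), but oxidative phosphorylation (adjusted p = 0.269), fatty acid oxidation (0.14), LXR target and lysosome genes (0.0826 for each) no longer passed. The MHC class I list, which had not passed (adjusted p = 0.168), did so with the covariate (adjusted p = 3.07e-04, 6 of 19 higher). Mitochondrially encoded genes, which had not passed either (adjusted p = 0.376), passed in opposite directions: as lower with the covariate (adjusted p = 0.0398) and as higher without WT M0 replicate 2 (adjusted p = 0.0216). When both M0 libraries numbered 2 were exchanged between genotypes, 33 oxidative phosphorylation genes were lower and 1 higher, and 10 fatty acid oxidation genes were lower. Of the glycolysis list, 16 were then lower and 3 higher, of the LXR targets 7 lower, and of the lysosomal genes 16 lower and 4 higher. Of the tricarboxylic acid cycle genes, 7 were lower and 2 higher. The exchange left the other libraries of each genotype in place, so it cannot decide whether these decreases go with the genotype. With it, 22 of 36 type I interferon-stimulated genes were also still higher, against 35 for the genotypes. Of the interferon-γ-induced GTPases and regulators, 15 were then higher and 2 lower, against 17 higher for the genotypes.

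Signalling lists passed as lower in TRα1PV M0, although not with an estimated correlation. For TLR and NF-kB signalling, 1 member was higher and 15 lower of 31 tested (4 and 16 adjusted over the list alone), with Bcl3 at -0.66 ± 0.09 and Tnfaip3 at -0.38 ± 0.07 (adjusted p = 0.00837, and adjusted p = 0.444 with an estimated correlation). With both M0 libraries numbered 2 exchanged between genotypes, 17 members of this list were lower and 3 higher. For immediate-early and heat-shock genes, 1 member was higher and 6 lower of 13 tested (1 and 6 adjusted over the list alone). Their adjusted p was 0.0116, with an adjusted p of 0.31 with an estimated correlation and of 0.0826 with the covariate. Lists that did not pass as a whole held single changes: the chemokine genes Cxcl10 (2.08 ± 0.22) and Ccl12 (2.62 ± 0.33) and Il18 (0.87 ± 0.12) were higher, the ectoenzyme gene Cd38 was lower (-2.76 ± 0.29) and Tnfsf10 higher (1.76 ± 0.20). The scavenger protein gene Cd5l (-1.59 ± 0.14), Tgm2 (-1.14 ± 0.11), Cish (-1.84 ± 0.20) and the clock output gene Dbp (-1.73 ± 0.13) were lower, and Fcgr4 (0.79 ± 0.08), Colec12 (0.88 ± 0.10) and Slco2b1 (1.28 ± 0.13) higher. In all, 1876 genes were higher and 2196 lower in TRα1PV M0, of which 319 and 216 passed 2-fold. The count of 4072 was 6131 without WT M0 replicate 2, 6415 without both M0 libraries numbered 2, and 2458 when only the 10 M0 libraries were fitted.

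**Figure D3:**
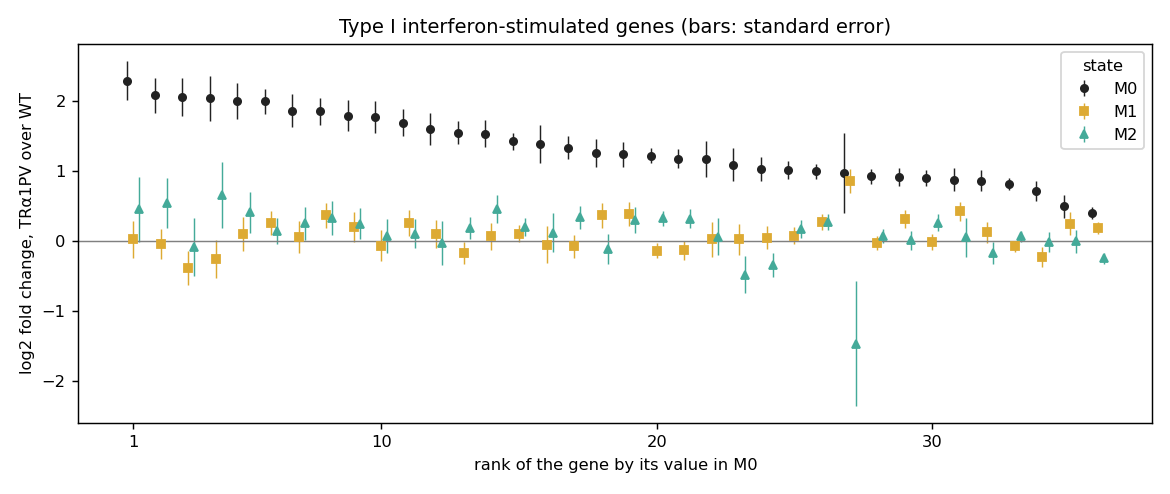
Log2 fold change between TRα1PV and WT of the 36 type I interferon-stimulated genes in M0, M1 and M2, with standard errors as bars and genes ordered by their value in M0. In M0, 35 genes were called higher, and in M1 and M2 most values lay near 0.

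In M1, stimulated with LPS and interferon-γ, the MHC class II list passed as lower in TRα1PV cells and the list of anti-inflammatory mediators as higher, neither with an estimated correlation (adjusted p = 0.229 and 0.0965). The MHC class I list did not pass (adjusted p = 0.636, with 2 of 19 lower, 1 adjusted over the list alone). Of the MHC class II genes, 6 of 12 tested members were lower (7 beside 1 higher adjusted over the list alone): the transactivator Ciita (-2.07 ± 0.25), H2-Eb1 (-1.96 ± 0.33), H2-Aa (-1.74 ± 0.33) and the invariant chain Cd74 (-1.26 ± 0.26) led them (adjusted p = 1.21e-04). Of the anti-inflammatory and feedback mediators, 7 members were higher and 1 lower of 17 tested (8 and 1 adjusted over the list alone), with Il10 (1.89 ± 0.19, 3.7-fold), Il4ra (1.1 ± 0.13) and Dusp1 (0.93 ± 0.13) higher and Ido1 lower (-1.96 ± 0.28). That list had an adjusted p of 4.64e-04. Of the dendritic cell markers, 3 of 10 tested members were lower in M1 (adjusted p = 0.15, and 0.0143 as the adjusted p with fry). Of the stromal markers, 4 of 8 were lower (adjusted p = 0.131).

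Inflammatory cytokine genes went both ways in M1. The 5 lower genes of this list were Il1b (-1.66 ± 0.24), Il6 (-0.81 ± 0.22), Il1a (-0.71 ± 0.20), Il12b (-0.68 ± 0.24) and Tnf (-0.52 ± 0.15), and the 3 higher were Ccl4 (1.03 ± 0.17), Ccl3 (0.68 ± 0.15) and Osm (0.50 ± 0.12). Of 23 tested, 4 and 5 were higher and lower adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.585). Il6, Il1a, Il12b and Tnf were chosen after their values were seen. Over their alternatives the adjusted p of Il6 ranged from 2.82e-04 to 0.0528, of Tnf from 0.00138 to 0.0666 and of Il12b from 2.49e-05 to 0.366. Without WT M1 replicate 5, Il6 (adjusted p = 0.0528), Tnf (0.0586) and Il12b (0.114) lost their call, as did Tnf without either M1 library numbered 2 and Il12b without TRα1PV M1 replicate 1, either M1 library numbered 2, 3 or 4, or with DESeq2 (adjusted p = 0.366). Of the classical activation genes, 1 member was higher and 10 lower of 25 tested (3 and 10 adjusted over the list alone), with Cd38 (-0.95 ± 0.15) and the costimulatory genes Cd80 (-0.70 ± 0.14) and Cd86 (-0.47 ± 0.10) lower and Tnfsf9 higher (0.78 ± 0.15). For TLR and NF-kB signalling, 3 members were higher and 10 lower of 31 tested (4 and 13 adjusted over the list alone), with Irak3 at -0.65 ± 0.10 and the LPS co-receptor gene Cd14 at -1.03 ± 0.19. The adjusted p was 0.0127 and 0.0127, and 0.522 and 0.572 with an estimated correlation.

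The gene with the smallest p in M1 was Klf9, which stood at 0.747 ± 0.173 CPM in TRα1PV and 27.5 ± 5.83 CPM in WT (-5.19 ± 0.17, 36.4-fold lower, adjusted p = 1.16e-19). Intu (-1.78 ± 0.09), Hacd3 (-1.34 ± 0.09), the adaptor gene Blnk (-1.12 ± 0.08), Cuedc1 (-1.61 ± 0.13), the cyclin gene Ccnd2 (-1.78 ± 0.14), Mmp8 (-3.01 ± 0.25) and Gnptab (-0.88 ± 0.08) were also lower. The largest changes included Bgn (-4.01 ± 0.77), Col1a2 (-3.20 ± 1.13) and Mmp27 (-2.59 ± 0.30) among the decreases and the adenylyl cyclase gene Adcy2 (3.22 ± 0.46) among the increases. Kcnd3 had no read in TRα1PV and 11 in WT, at least 3.7-fold lower, and Slc36a2 had 13 reads in TRα1PV and 1 in WT, a ratio of 12.9 (95% exact interval 1.94 to 548). Col1a2 lost its call with limma-voom (adjusted p = 0.11) and without WT M1 replicate 2, 4 or 5 or TRα1PV M1 replicate 1, 3 or 5 (adjusted p = 0.0588 without WT M1 replicate 4), with a range from 0.00297 to 0.11.

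Genes of thyroid hormone signalling were among those that changed in M1. For receptors, transporters and cofactors, 6 members were higher and 1 lower of 23 tested (7 and 1 adjusted over the list alone), with the retinoid X receptor gene Rxra at 0.75 ± 0.08 (adjusted p = 0.0127, and adjusted p = 0.0965 with an estimated correlation). For T3-responsive genes, 1 member was higher and 4 lower of 15 tested (1 and 6 adjusted over the list alone), with Cpt1a at -0.43 ± 0.07 after Klf9 (adjusted p = 0.0393, and adjusted p = 0.141 with an estimated correlation). For phagocytosis and scavenger receptors, 9 members were higher and 3 lower of 24 tested (9 and 3 adjusted over the list alone), with the inhibitory Fc receptor gene Fcgr2b (1.31 ± 0.12) and Colec12 (1.18 ± 0.11) higher and Cd5l lower (-1.57 ± 0.14). Of the unfolded protein and integrated stress response genes, 7 of 19 tested members were higher (7 adjusted over the list alone), with Atf3 at 0.29 ± 0.07. The adjusted p of the last pair of lists was 0.021 and 0.0127, and 0.465 and 0.522 with an estimated correlation. Of the interferon-γ-induced GTPases, 2 of 22 tested members were lower (1 adjusted over the list alone), led by Tgtp1 (-0.83 ± 0.14), with an adjusted p of 0.014 for the list and of 0.624 with an estimated correlation. Of the type I interferon-stimulated genes, 2 of 36 tested members were higher (1 adjusted over the list alone). They were led by Ifnb1 (0.86 ± 0.17), a list member that encodes interferon-β itself, and the list did not pass (adjusted p = 0.15). Single genes of other lists were higher, such as Pdcd1lg2 (0.92 ± 0.12), Ptgs1 (0.97 ± 0.15) and F13a1 (1.18 ± 0.13), or lower, such as Cish (-0.97 ± 0.13), the transferrin receptor gene Tfrc (-1.08 ± 0.16), Vegfa (-1.06 ± 0.13), Sparc (-2.37 ± 0.56) and Dbp (-1.06 ± 0.16). In all, 1528 genes were higher and 1604 lower, of which 167 and 140 passed 2-fold. The count of 3132 became 5467 with the share of reads outside genes as a covariate, which included 3126 of the 3132. With that covariate the TLR (adjusted p = 0.0519) and T3-responsive lists (adjusted p = 0.11) no longer passed.

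In M2, stimulated with interleukin-4, the cholesterol synthesis list passed as higher in TRα1PV cells and the MHC class II and NF-kB lists as lower, although none of them with an estimated correlation (adjusted p = 0.393, 0.497 and 0.393). Of the cholesterol biosynthesis genes, 12 of 24 tested members were higher (14 adjusted over the list alone), among them Hmgcs1 (0.61 ± 0.12) and Insig1 (0.53 ± 0.11). For TLR and NF-kB signalling, 1 member was higher and 13 lower of 31 tested (3 and 17 adjusted over the list alone), with Bcl3 at -0.85 ± 0.09 and the adhesion molecule gene Icam1 at -1.01 ± 0.11. Of the MHC class II genes, 6 of 12 tested members were lower (7 adjusted over the list alone), led by H2-Ab1 (-1.26 ± 0.29) and Ciita (-1.03 ± 0.24). The adjusted p of these lists was 1.35e-08, 1.21e-05 and 0.00576.

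For thyroid hormone receptors, transporters and cofactors in M2, 4 of 23 tested members were higher (8 beside 1 lower adjusted over the list alone), with the transporter gene Slco2b1 at 1.73 ± 0.13 and Rxra at 0.36 ± 0.08 beside Thra. This was the only list of the 3 genotype comparisons whose call held with an estimated correlation (adjusted p = 0.00344 and 0.0476). Thra, the gene of the mutated receptor, belongs to this list, which was not tested without it in any state. The T3-responsive genes Klf9 (-2.31 ± 0.12, 14.3 ± 2.05 against 70.4 ± 8.3 CPM) and Hr, the hairless corepressor gene (-2.92 ± 0.27), were lower. Their list did not pass as a whole with camera (adjusted p = 0.162), but passed as lower with fry (adjusted p = 1.44e-08). Ighm (-4.68 ± 0.17), Asb4 (-4.54 ± 0.24), Rin2 (-1.79 ± 0.10), Cuedc1 (-2.34 ± 0.15), Mmp8 (-3.24 ± 0.22), Traf3ip2 (-1.88 ± 0.13), the kinase gene Fgr (-2.31 ± 0.16) and Gdf3 (-3.60 ± 0.38) were lower. Col1a2 (-4.99 ± 0.75), Bgn (-4.04 ± 0.64) and Col6a3 (-3.87 ± 0.55) were lower as well, beside 5 of 8 stromal markers (6 adjusted over the list alone), such as Sparc (-3.69 ± 0.49) and Acta2 (-1.62 ± 0.23).

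Of the neutrophil and granulocyte-precursor markers in M2, 6 members were higher and 2 lower of 12 tested (9 and 2 adjusted over the list alone), with S100a8 (1.83 ± 0.31) and Ngp (1.57 ± 0.34) higher and Csf3r (-0.85 ± 0.09) lower. Of the inflammatory monocyte markers, 3 members were higher and 1 lower of 10 tested (4 and 1 adjusted over the list alone), with F13a1 (1.61 ± 0.11) higher. That list did not pass (adjusted p = 0.0503), but did so with a replicate block (adjusted p = 0.0219). The stromal and granulocyte lists had an adjusted p of 7.84e-05 and 0.0256, and of 0.393 and 0.637 with an estimated correlation. For glycolysis and HIF-1 targets, 2 members were higher and 8 lower of 28 tested (3 and 13 adjusted over the list alone), with Vegfa (-1.63 ± 0.14), Pfkfb3 (-0.65 ± 0.09) and Hk3 (-0.58 ± 0.10) lower. Of the cell cycle genes, 5 of 30 tested members were lower (5 adjusted over the list alone), led by Mcm3 (-0.40 ± 0.10), and for classical activation genes, 1 member was higher and 7 lower of 25 tested (2 and 7 adjusted over the list alone), led by Acod1, the itaconate synthase gene (-1.24 ± 0.23). The adjusted p of these lists was 4.62e-04, 1.21e-05 and 0.0286, and 0.497, 0.567 and 0.567 with an estimated correlation. Smaller changes made up the oxidative phosphorylation list (2 of 55 lower, which did not pass over the list alone, adjusted p = 0.00218), the MHC class I list (2 of 19 lower, 2 over the list alone, adjusted p = 0.0327) and the oxidative stress list (2 of 19 lower, 3 over the list alone, adjusted p = 0.0179), none of which passed with an estimated correlation (adjusted p = 0.715, 0.715 and 0.567). The mitochondrially encoded genes passed as a list in opposite directions in M2 and M1, although single members did not pass. They were higher in M2 (median 0.48, adjusted p = 0.00218, and adjusted p = 0.637 with an estimated correlation) and lower in M1 (median -0.56, adjusted p = 0.0393, and adjusted p = 0.841 with an estimated correlation). With the share of reads outside genes as a covariate, the M2 calls of the mitochondrial (adjusted p = 0.248), oxidative phosphorylation (0.255) and MHC class I lists (0.228) were lost. Mitochondrial reads made up 3.38 ± 0.570% in TRα1PV and 2.49 ± 0.802% in WT (exact permutation p = 0.0873, n = 5 per group), and reads outside genes 10.5 ± 0.833% and 9.47 ± 0.734% (exact permutation p = 0.0714, n = 5 per group).

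Within the alternative activation list, single genes differed between genotypes in M2: Tgm2 (-1.04 ± 0.11) and Cish (-0.87 ± 0.12) were lower and the arginine transporter gene Slc7a2 (0.85 ± 0.11) higher, and the list did not pass (adjusted p = 0.371). The chemokine gene Ccl12 (1.45 ± 0.26) and Colec12 (0.99 ± 0.10) were higher, and Cxcl16 (-0.75 ± 0.07), Cd5l (-1.55 ± 0.14) and Dbp (-1.38 ± 0.14) lower. The type I interferon list did not pass in M2 (adjusted p = 0.335), and the 1 of 36 members called higher did not pass over the list alone. Lists that passed in none of the 3 genotype comparisons were macrophage identity (adjusted p = 0.376 in M0, 0.131 in M1 and 0.379 in M2), dendritic cell markers (0.471, 0.15 and 0.76), osteoclast markers (0.278, 0.555 and 0.162), circadian clock genes (0.521, 0.541 and 0.832), cytokines (0.29, 0.585 and 0.832) and alternative activation (0.845, 0.541 and 0.371). These are camera values with the preset correlation, and some of these lists passed with fry, such as osteoclast markers in M0 (adjusted p = 0.00531). In all, 963 genes were higher and 1092 lower, of which 136 and 177 passed 2-fold. The count of 2055 was 1275 without WT M2 replicate 5 and 4008 when only the 10 M2 libraries were fitted.

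**Figure D4:**
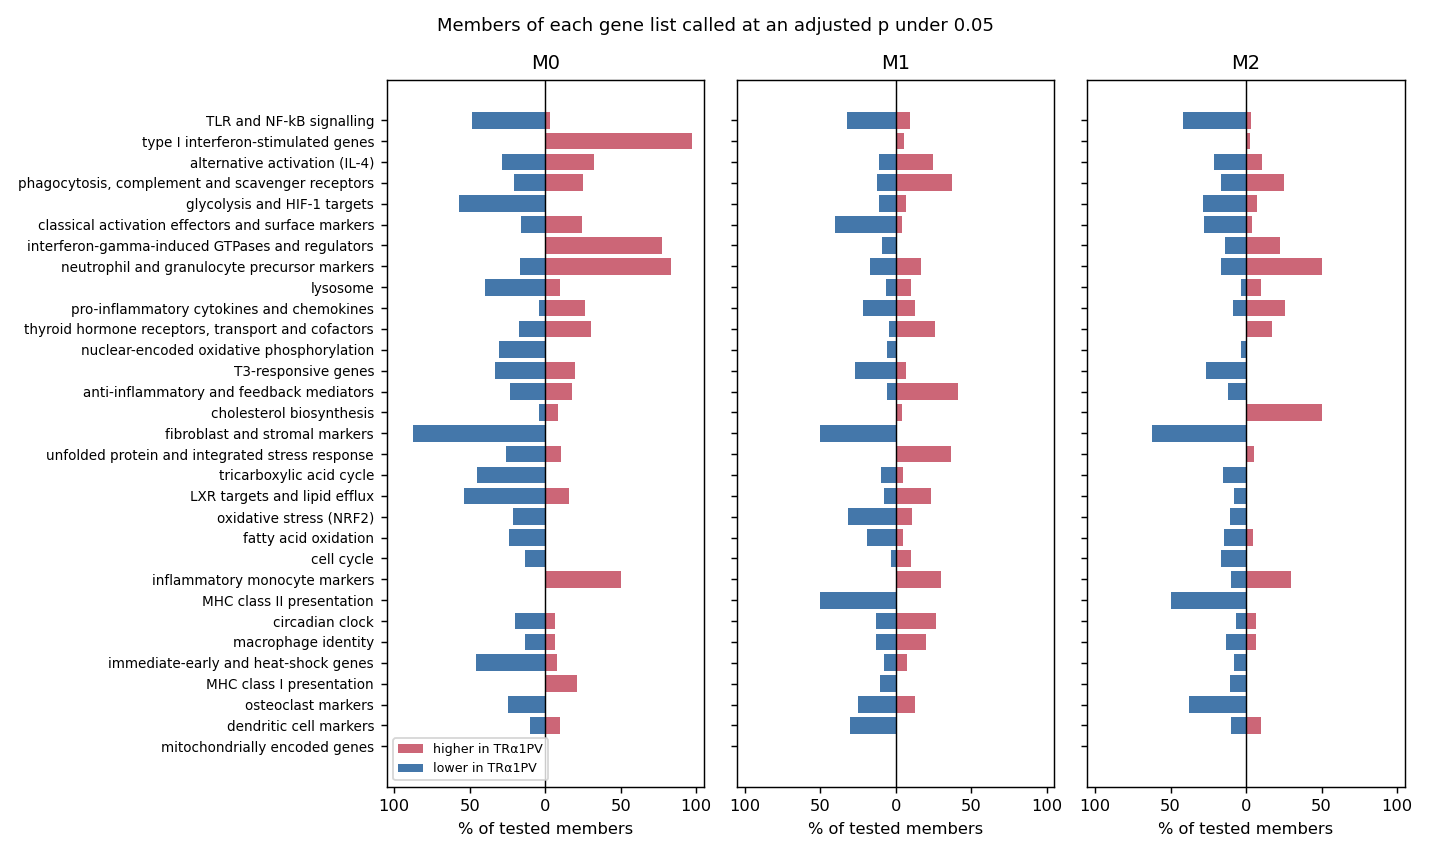
Percent of the tested members of each of the 31 gene lists that were called higher (right) or lower (left) in TRα1PV than in WT, in M0, M1 and M2. The type I interferon list stood at 35 of 36 members higher in M0 and at 2 of 36 in M1.

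The genotype effect itself was then compared between states. It is the signed log2 fold change of TRα1PV over WT, so a higher effect can stand for a smaller decrease. The interferon difference of M0 was smaller in the stimulated states: 32 of 36 type I interferon-stimulated genes had a lower genotype effect in M1 than in M0 (33 adjusted over the list alone), and 27 a lower effect in M2 than in M0 (35 over the list alone). In M2 against M0 this held with an estimated correlation for the type I list (adjusted p = 7.70e-49, and 0.0196 as the adjusted p with an estimated correlation) and for the GTPases (12 of 22 lower, 16 over the list alone, adjusted p = 2.97e-22 and 0.0117). In M1 against M0 it did not (adjusted p = 1.79e-23 and 0.289 for the type I list, 2.17e-13 and 0.128 for the GTPases). Glycolysis and HIF-1 targets had a higher genotype effect in M1 than in M0 for 14 of 28 genes and a lower one for 1 (18 and 1 over the list alone, adjusted p = 5.74e-06, and adjusted p = 0.394 with an estimated correlation). Their median log2 fold change was -0.38 in M0 and 0.07 in M1, so the median decrease of M0 was absent in M1.

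Among single genes, Ighm (4.52 ± 0.35), Rin2 (1.62 ± 0.13), Trp53inp2 (0.88 ± 0.08) and Apobec1 (0.71 ± 0.07) had a higher genotype effect in M1 than in M0, and Intu (-1.37 ± 0.13) and Hacd3 (-1.24 ± 0.12) a lower one. Ighm, Rin2 and Trp53inp2 were lower in TRα1PV M0, so for them this stands for a smaller or absent decrease. Between M2 and M0, the genotype effect was higher for Nid1 (3.98 ± 0.50) and Klf9 (1.51 ± 0.19) and lower for Ifi47 (-1.40 ± 0.17), the sulfotransferase gene Tpst1 (-0.89 ± 0.12), Tagap (-1.45 ± 0.20) and Mx1 (-1.86 ± 0.26). For Klf9 this was a smaller decrease in M2 (-2.31) than in M0 (-3.81). The effect on Thra did not differ detectably in M1 (-0.26 ± 0.14, adjusted p = 0.155) or M2 (0.17 ± 0.14, adjusted p = 0.762), nor did that on Thrb (adjusted p = 0.451 and 0.334). In all, 2091 genes had a higher and 2084 a lower genotype effect in M1 than in M0, against 110 and 229 in M2. The count of 339 for M2 was 533 without WT M0 replicate 2.

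Calls overlapped most between M0 and M2. Of the genes higher in TRα1PV, 542 were shared by M0 and M2, where independent lists of that size would share 115, and of those lower, 721 against 153. M0 and M1 shared 250 higher genes against 183 and 423 lower genes against 225, while 377 genes changed in opposite directions. In all 3 states, 110 genes were higher and 198 lower in TRα1PV, where independent lists would share 11.2 and 15.6. The mean share of reads outside genes was higher in TRα1PV in each state, and the figures for independent lists do not allow for such a trend. With that share as a covariate, 58.3% of the calls in M0, 99.8% in M1 and 66.8% in M2 were kept. The overlaps were not counted again with it. Klf9, Mmp8, Bgn, Col1a2, Cd5l, Vegfa and Dbp were among the lower genes, and F13a1 was among the higher.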

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

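The tests for endotoxin, for carry-over, for a lower share of macrophages and for exchanged labels, the covariate fit, and the other tools for M2 groupings, were chosen after the results were seen. Library measures, mean levels of lists and levels of named genes were searched for a library far from the other 4 of its group, and chance finds this in about 1 of 20 groups. It was found in 4 of 48 groups of library measures (2.4 by chance), 11 of 186 of lists (9.3) and 24 of 474 of genes (23.7).

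Type I interferon-stimulated genes were higher in TRα1PV M0, by more than in M1 or M2. A trend in library quality as their whole cause was argued against, since with the share of reads outside genes as a covariate 35 of 36 members were still called higher, with a median log2 fold change of 1.356 (median SE 0.205) against 1.253 (0.179) without it, while 1700 other calls were lost and 724 gained. For endotoxin, of 24 TLR and NF-kB genes that rose with LPS and interferon-γ in WT, 1 was higher and 13 were lower in TRα1PV M0 (median -0.22). This argued against stimulation that raises these genes as in M1. Their M0 values were known when the test was written, and a weaker or earlier exposure to endotoxin was not tested. Carry-over of RNA from M1 cultures was argued against, because the 10 genes with the largest M1 increase implied a median of 4.82e-05% M1 RNA (-0.0156 to 0.0379%), against a median of 8.38% (quartiles 3.04 and 18.1%) implied by the interferon-stimulated genes. An effect of the genotype on interferon signalling in resting cells may remain as a hypothesis, and culture conditions that the labels do not give were not tested.

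Granulocyte-precursor markers were higher and stromal markers lower in TRα1PV M0. A lower share of macrophages that raises all other cells alike would raise both. The stromal median was -3.456 (SE 0.773 over members) and the granulocyte median 1.22, so it cannot account for both. As the pattern itself held these directions, this was no separate test. A lower share with more granulocyte precursors and fewer stromal cells was not tested. Residual granulocyte precursors may contribute, as their 10 higher markers varied together between cultures of a group (mean correlation 0.862, where 99% of random lists lay under 0.264). Genes regulated together within macrophages could vary together as well, so this correlation does not tell residual cells from such a change. Mmp8 and Csf3r of the same marker list were lower and did not enter this correlation. The most abundant of the 10 higher markers stood at 76.4 (S100a9), 66.2 (Ngp) and 53.8 CPM (S100a8) in TRα1PV and at 33.1, 28.1 and 18.6 CPM in WT, and no sort that would remove such cells is described. Residual stromal cells cannot be told apart from a change within macrophages either. Their correlation of 0.485 (random lists under 0.259) fell just short of the 0.5 set as the bound. The levels were also low (Acta2 1.251 CPM in TRα1PV against 4.481 in WT, Col1a2 0.0611 against 3.398).

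Exchanging both M0 libraries numbered 2 between genotypes called 5740 genes, more than the 4072 of the genotypes, and 2581 were called alike by both. Exchanged labels were argued against, because over 414 genes changed alike in M1 and M2, WT M0 replicate 2 lay nearer to TRα1PV at 23.2% (above the 20% set as the bound) and its partner, which was not part of that bound, at 13.5%, within the 9.42 to 17.9% of the other 8 libraries. A library-quality trend may account for the pattern: with the share of reads outside genes as a covariate, edgeR called 0 genes for the exchanged grouping (1838 at an unadjusted p under 0.05, 31 with limma-voom). The median absolute log2 fold change of its genes went from 0.38 (SE 0.10) to 0.18 (SE 0.11), so the calls ended by smaller changes. The share correlated with the exchanged grouping (0.775) more than with the genotypes (0.548), which also costs the covariate fit power, and with it 3096 genes were called for the genotypes, of which 2372 were among the 4072.

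For the number of genes called, 100 groupings of the libraries were tried per comparison, the real one included. A chance division of the libraries was argued against in M1, where the real grouping alone, 1 of 100, called as many (3132, highest other 2159). The same held in M2, also 1 of 100 (2055, highest other 974). In M0, 4 of 100 groupings called as many, the real one included (4072, highest other 5740). This met the bound set for it, but each of the 3 others called more genes, so the count alone does not exclude chance. Each of them grouped WT M0 replicate 2 with at least 3 TRα1PV libraries. The same limit applied to the difference of the genotype effect. Between M1 and M0, 2 groupings called as many (4175 and 4520), and between M2 and M0, also 2 (339 and 1801). In both, the other grouping again placed WT M0 replicate 2 with at least 3 TRα1PV libraries, but it also moved M1 or M2 libraries. Whether the M0 libraries alone raised these counts was not tested. For polarization, the real grouping alone, 1 of 100, called as many: 12487 against 8489 for M1 and 8213 against 4553 for M2 in WT, and 12658 against 8770 and 9046 against 4056 in TRα1PV. Among groupings that parted all 5 same-numbered pairs, the highest count was 5740 in M0, 463 in M1, 8489 for M1 and 3982 for M2 in WT, and 8607 and 3960 in TRα1PV. For the genotypes in M2, each of the 12 such groupings gave 0 genes with edgeR (197 to 2783 at an unadjusted p under 0.05) and 0 with limma-voom, and the highest count with DESeq2 was 115.

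The libraries standing apart in a measure were WT M2 replicate 3 with 23 M gene reads (23016000), WT M2 replicate 4 with 10.8% of reads outside genes, TRα1PV M0 replicate 5 with 4.22% unaligned reads and WT M0 replicate 2 with 1.12% low-quality reads. Among mean log2 CPM of lists, WT M0 replicate 2 was low for fatty acid oxidation (4.95) and lysosome (9.19), and WT M0 replicate 1 high for cell cycle (3.01) and osteoclast markers (3.34). TRα1PV M0 replicate 1 was high for cell cycle (2.77), WT M1 replicate 1 low for dendritic cell markers (0.06) and WT M1 replicate 4 low for LXR targets (4.28). WT M2 replicate 4 was low for fatty acid oxidation (5.46) and macrophage identity (9.19), TRα1PV M2 replicate 3 low for the unfolded protein response (5.73) and TRα1PV M2 replicate 4 high for thyroid hormone receptors and cofactors (5.63).

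Single genes with a library standing apart are given as its log2 CPM. In WT M0 they were Hk3 (7.03, low) and Il27 (-1.11, low) in replicate 2 and Ighm (7.59, low) and Ncf1 (8.87, low) in replicate 5. In TRα1PV M0 they were Cx3cr1 (1.77, low) in replicate 4 and Ctsc (9.35, low) and Klf4 (1.93, low) in replicate 5. WT M1 had Il1a (4.66, low) in replicate 1, Dusp1 (6.38, low) in replicate 4, and Slc36a2 (-3.43), Agmo (-3.46) and Thrb (-3.40), each with a read in 1 library, in replicates 2, 4 and 5. TRα1PV M1 had Il15ra (8.43, high) and Sparc (-1.89, high) in replicate 1, Osm (5.53, low) and Abca6 (-3.43, a read in 1 library) in replicate 4, and Ccnd2 (6.70), Il6 (4.79), Ptgs2 (11.76) and Slamf7 (11.41) high in replicate 5. In M2 they were Rxra (6.56, low) in WT replicate 1, Pdcd1lg2 (6.11, low) in WT replicate 4, Traf3ip2 (0.73, low) in TRα1PV replicate 2 and Csf3r (7.39, high) in TRα1PV replicate 5.

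The genotype effect differed between M1 and M0, by the test of the difference in edgeR, for Apobec1 (0.71), Cd38 (1.81), Cish (0.87), Dbp (0.67), Gnptab (0.47), Ighm (4.52), Mmp8 (1.47), Rin2 (1.62), Trp53inp2 (0.88) and Vegfa (0.94), and for Hacd3 (-1.24), Intu (-1.37) and Klf9 (-1.37). Between M2 and M0 it differed for Cish (0.97), Klf9 (1.51), Mmp8 (1.24), Nid1 (3.98), Ifi47 (-1.40), Mx1 (-1.86), Tagap (-1.45) and Tpst1 (-0.89). Lists whose test of the difference passed with a preset correlation are given as the median difference. Between M1 and M0 these were anti-inflammatory mediators (0.32), stromal markers (1.79), glycolysis (0.43), immediate-early genes (0.33), LXR targets (0.50), lysosome (0.20), oxidative phosphorylation (0.19) and the unfolded protein response (0.25), and below 0 classical activation (-0.33), interferon-γ-induced GTPases (-1.16), MHC class II (-0.59), mitochondrially encoded (-0.57) and type I interferon-stimulated genes (-1.31). Without WT M0 replicate 2, the differences of classical activation (adjusted p = 0.0727), MHC class II and anti-inflammatory mediators (adjusted p = 0.0612 each) and immediate-early genes and stromal markers (adjusted p = 0.0645 each) no longer passed. With the share of reads outside genes as a covariate, classical activation and immediate-early genes (adjusted p = 0.0979 each), oxidative phosphorylation (adjusted p = 0.138) and mitochondrially encoded genes (adjusted p = 0.263) did not. Between M2 and M0 they were cholesterol synthesis (0.25), fatty acid oxidation (0.06), glycolysis (0.16), immediate-early genes (0.07), LXR targets (0.35), lysosome (0.14), oxidative phosphorylation (0.08), the tricarboxylic acid cycle (0.10) and the unfolded protein response (0.11, with a mean of -0.02). Below 0 were cell cycle (-0.25), classical activation (-0.30), GTPases (-0.91), MHC class I (-0.19), MHC class II (-0.50) and type I interferon-stimulated genes (-1.25). With the covariate, oxidative phosphorylation (adjusted p = 0.651), fatty acid oxidation (adjusted p = 0.315, and 0.0694 with a replicate block) and immediate-early genes (adjusted p = 0.0813) no longer passed between M2 and M0, and mitochondrially encoded genes did (adjusted p = 1.84e-04). With an estimated correlation, the difference held for the type I interferon-stimulated genes (adjusted p = 0.0196) and the GTPases (adjusted p = 0.0117) between M2 and M0 and for no other of these lists.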

How the results depend on the processing

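The covariate fit, and the fits without both M0 libraries numbered 2 or, for lists, without WT M0 replicate 2, were chosen after seeing the data. The 4 counts of genes called for polarization stayed within 1.5 times under every alternative, at 11056 to 13979 (M1) and 6985 to 8783 (M2) in WT and 11986 to 14570 and 8581 to 9314 in TRα1PV. With the share of reads outside genes as a covariate, the count went from 3132 to 5467 in M1 and from 339 to 579 for the difference between M2 and M0. Without both M0 libraries numbered 2, it went from 4072 to 6415 in M0 and from 4175 to 6329 for the difference between M1 and M0. DESeq2 gave 527 for the difference between M2 and M0. The share of higher calls for this difference was 32.4%, and it ranged over the alternatives from 24.2% without a filter on low counts to 47.1% without both M0 libraries numbered 2. With the libraries of the compared groups alone, and so fewer residual degrees of freedom and a separate dispersion, the count was 2458 in M0 and 4008 in M2. For these counts the cause was not tested. Leaving out 1 library gave 2940 (without WT M0 replicate 4) to 6131 (without WT M0 replicate 2) in M0, 2183 to 3534 in M1, 1275 (without WT M2 replicate 5) to 2723 (without WT M2 replicate 4) in M2, 3168 to 6000 for the difference between M1 and M0, and 253 (without TRα1PV M2 replicate 2) to 533 (without WT M0 replicate 2) for that between M2 and M0. Of the 254 values of named genes, all kept their side of the threshold with RLE size factors, and none reversed under any alternative. The calls lost were Thrb in M0 (no filter, compared groups alone and without both M0 libraries numbered 2), Scd1 (limma-voom and the covariate), Col1a2 in M1 (limma-voom) and Il12b (DESeq2 and compared groups alone). Among 2700 values with 1 library left out, 26 calls were lost and 2 gained. The replicate block gave a call to Thra for M1 against M0 in TRα1PV (adjusted p = 0.0295) and changed no other call of a named gene. In lists, it gave a call to the tricarboxylic acid cycle (adjusted p = 0.0482) and stromal markers (adjusted p = 0.0389) in M1, to monocyte markers in M2 (adjusted p = 0.0219) and to granulocyte markers in the 4 polarization comparisons (adjusted p = 0.00761, 0.0281, 0.0123 and 0.0493), and ended that of fatty acid oxidation between M2 and M0 (adjusted p = 0.0694). Of 279 list tests, 108 lost their call with an estimated correlation, 23 lost and 69 gained one with fry, and 21 lost and 3 gained one with the covariate. Without WT M0 replicate 2, 5 of 155 lost a call and 2 gained one. Depth limited genes with few reads, such as Thrb in M1, Kcnd3 and Slc36a2, and in the simulated data 78% of 2-fold changes were found.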

Other observations

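The choice to describe the list tests below was made after the results were seen. LPS with interferon-γ raised 36 of 36 type I interferon-stimulated genes in WT and 35 in TRα1PV (36 and 35 adjusted over the list alone), 19 of 19 MHC class I genes in both and 25 of 28 glycolysis genes and HIF-1 targets in both. Lower were 1 of the interferon-stimulated genes in TRα1PV and 3 of the glycolysis list in WT and 1 in TRα1PV. The adjusted p was 5.39e-16 and 1.39e-11 for the interferon list, 1.40e-10 and 1.61e-09 for MHC class I and 3.12e-08 and 4.69e-09 for glycolysis. With an estimated correlation it was 0.252 and 0.4, 0.179 and 0.165, and 0.179 and 0.151.

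Interleukin-4 raised 24 of 24 cholesterol biosynthesis genes in both genotypes, 53 of 55 nuclear genes for oxidative phosphorylation in both (1 was lower in each), 16 of 20 tricarboxylic acid cycle genes in both, and 29 of 30 cell cycle genes in WT and 27 in TRα1PV. The adjusted p with an estimated correlation was 0.0426 in WT and 0.0603 in TRα1PV for cholesterol synthesis, 0.0408 and 0.0392 for the tricarboxylic acid cycle, 0.125 and 0.158 for oxidative phosphorylation and 0.173 and 0.278 for the cell cycle. Type I interferon-stimulated genes fell in M2 against M0 in 24 of 36 cases in WT, where 4 were higher, and in 34 in TRα1PV (26 lower with 4 higher, and 35 lower, adjusted over the list alone), with an adjusted p of 2.06e-04 and 1.3e-15, and of 0.545 and 0.218 with an estimated correlation.

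A hypothesis was that TRα1PV cells respond less to stimulation over all responding genes. The slope of the TRα1PV response on the WT response was 1.012 for M1 over 13405 genes (exact permutation p = 0.298), and 1.082 for M2 over 10361 genes (exact permutation p = 0.00532, n = 5 per group, 63504 arrangements from 0.899 to 1.11). Neither slope lay below 1, which argued against a smaller response, although that for M2 differed from 1 by more than the 5% set as the bound for no difference. Slopes run across genes, which are not independent replicates.

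Among 40 tested genes nearest to Thra on the chromosome, 3 were higher and 7 lower in TRα1PV M0, where the share of all genes would give 4.78 higher. In M1, 7 were higher and 6 lower, where that share would give 3.90 higher, and in M2, 1 was higher and 7 were lower, where it would give 2.46 higher. Of all 15686 genes, 2196 were lower in M0, 1604 in M1 and 1092 in M2. The share of lower neighbours was above that of all genes in each state, most so in M2, and that of higher neighbours was above it in M1. These differences in shares were not tested. The median log2 fold change was -0.02 (SE 0.0843) in M0, -0.00283 (SE 0.0983) in M1 and -0.10 (SE 0.0844) in M2.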
